A study of Mus musculus with 6 samples.

How the data were processed

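Whole-liver RNA of 6 C57BL6/J mice, 3 given CBZ and 3 given DMSO, was analysed from 1-colour array files, 1 array per mouse. Groups and replicate numbers were taken from the labels. Per the labels' protocols, total RNA was isolated with RNeasy columns, and 100 ng of it was amplified and labelled with Cy3. Per the file headers and the submitters' processing notes, the authors extracted the scans with Agilent Feature Extraction, version 10.7.3.1 in the headers, with the protocol GE1_107_Sep09. The deposited scanner files give each spot as an intensity on a linear scale, and the processed intensity is already background-subtracted and detrended within the array, per the file headers. The deposited table of the authors' processed values holds a ratio of each spot's processed intensity to the array's median, since dividing the scanner values by that median gave the table back and each column had a median of 1. Its values are linear, its centring is the array median, and no direction is involved. Except under median scaling and the authors' table, with a variance common to all probes, single-gene p-values measure the spread between mice. Those of camera at a preset correlation set a list's genes against other genes, and do not measure that spread.

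The arrays carried 59305 spots apart from controls. Control spots and spots that the software marked as non-uniform or population outliers (114 to 126 per array) were left out, and 23 of 55681 probes had no usable spot on some array. The log2 of the processed intensity was scaled by subtracting each array's 75th percentile over the non-control spots, and spots of 1 probe were averaged. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 22352 probes. Probes were named from the accession or symbol in the files through a RefSeq gene table of the assembly GRCm38.p6, used for names only. Of the 55681 probes 27428 matched by accession, 3483 by symbol and 507 by synonym, and the other 24263 kept the name in the files. Coordinates are those of the array design, on mm9 (NCBI build 37). A gene was represented by its probe with the highest mean signal, and 4010 genes had more than 1 probe. Signal over background limits what dim probes can show, since the 75th percentile of an array was 9.89 to 12.3 times its median local background. Where no array of a group had a probe well above background, the fold is a bound, for the report's background subtraction only. It sets the mean of the brighter group against the mean, over the arrays of the other group, of the higher of the probe's own signal and the lowest signal of any probe well above background.

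CBZ was compared with DMSO with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all probes kept and a threshold of 0.05. Each value given as a log2 fold change is CBZ minus DMSO, ± its moderated standard error. Before the data were examined, 40 gene lists for liver pathways, drug response and cell types were fixed, and 39 had at least 5 measured genes. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists. Camera with an estimated correlation and fry were alternatives, and the members of each list were also adjusted over the list alone. The genes named were fixed by rule before the data were examined. They were, among genes past the threshold whose groups did not overlap, up to 12 rises and 12 falls by size and up to 3 per direction that were below background in 1 whole group, up to 4 genes with the smallest adjusted p from each list that was called or had 3 calls, the 8 smallest unadjusted p in a direction with fewer than 5 calls, and 9 genes in any case (Cyp2b10, Cyp3a11, Cyp1a1, Nqo1, Hmox1, Fos, Per1, Cyp7a1 and Alb). Clone names, predicted genes and bare accessions were counted and not named. One gene that the rule takes is not reported here. Other genes are said to have been chosen after their values were seen.

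Slide and scan date were the same for all arrays, so the row on the slide was the batch that could be tested, as a covariate. Alternatives fixed beforehand were normexp background correction (offset 50) of the mean and local background intensity, quantile and median scaling, no filter, a filter on all 6 arrays, an intensity trend with robust eBayes, the authors' table, the replicate number as a block, leaving out each mouse in turn, the mean of a gene's probes, an adjusted p under 0.10, and a fold of at least 2. Scaling over the spots detected on all arrays, and the array's median intensity as a covariate, were added after seeing the data. The fit was tested on simulated data, with the means and residual SDs of the 22352 probes and 200 probes changed in each of 10 runs. It called 56.9% of probes changed 2-fold, 92.2% of those changed 4-fold and 98.3% of those changed 8-fold in this comparison, 3.34% of its calls were on unchanged probes, and with nothing changed it called 0 probes. The simulated noise was independent between genes. A list shifted by 0.5 was called in 10 of 10 runs by camera at the preset correlation and in 9 with an estimated correlation. Figures were drawn with matplotlib 3.10.9.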

Results

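Gene expression was measured in whole liver of C57BL6/J mice, an inbred laboratory strain, 2 h after an oral dose. In 1 group, 3 mice received 250 mg/kg of a compound named only as CBZ in the labels, and in the other group 3 mice received dimethyl sulfoxide (DMSO), a common solvent. Total RNA from each liver was labelled with the dye Cy3 and hybridised to a 1-colour Agilent mouse array with 55681 distinct probes apart from controls. Between 42.6% and 45.8% of the spots of an array were well above background, the 75th percentile of its signal lay between 158 and 191 intensity units, and no spot was saturated. After probes that were dim in both groups had been left out, 22352 probes of 17047 genes were compared, and the number of arrays limits the precision of every value below. All 6 arrays lay on 1 slide, where the 3 DMSO arrays and CBZ replicate 1 shared row 1 while CBZ replicates 2 and 3 lay in row 2. The log2 signals of any pair of arrays correlated across probes with r between 0.988 and 0.993, and no pair of arrays held the same values.

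The comparison of CBZ with DMSO asked which liver transcripts differed 2 h after dosing. In the livers of CBZ-treated mice 8 genes rose and 1 fell. The largest of these rises was that of Gadd45b, a stress-inducible gene of the growth arrest and DNA damage family, which was 7.73-fold higher (log2 fold change 2.95 ± 0.20 SE, n = 3 mice per group). Myc, which encodes a transcription factor that drives cell growth, rose 3.12-fold (1.64 ± 0.18). Cyp2c55, a cytochrome P450 of drug and fatty acid metabolism, rose 2.91-fold (1.54 ± 0.18). Gpcpd1, which encodes a phosphodiesterase that cleaves glycerophosphocholine, rose 2.42-fold (1.27 ± 0.12), and Klhl25, a substrate adaptor of a cullin ubiquitin ligase, rose 2.09-fold (1.06 ± 0.13), with a dimmer second probe at 1.69 ± 0.14. The fall was that of Gdf9, a growth factor best known from oocytes, which was not well above background on any CBZ array and was at least 3.98-fold lower there. Normexp background correction gave smaller log2 fold changes of -1.06 for Gdf9 and 1.07 for Myc. The value for Gdf9 is a smaller fold than that bound, which therefore holds only for the background subtraction used here. In limma's moderated test the Benjamini-Hochberg adjusted p was 0.0056 for Gadd45b, 0.019 for Gpcpd1, 0.030 for both Myc and Gdf9, 0.033 for Cyp2c55 and 0.037 for Klhl25. For each of these genes the 3 CBZ values lay on one side of the 3 DMSO values, which the rule for naming them required. Over all genes 12.9% separated the groups in this way, where chance gives 10%.

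**Figure D1:**
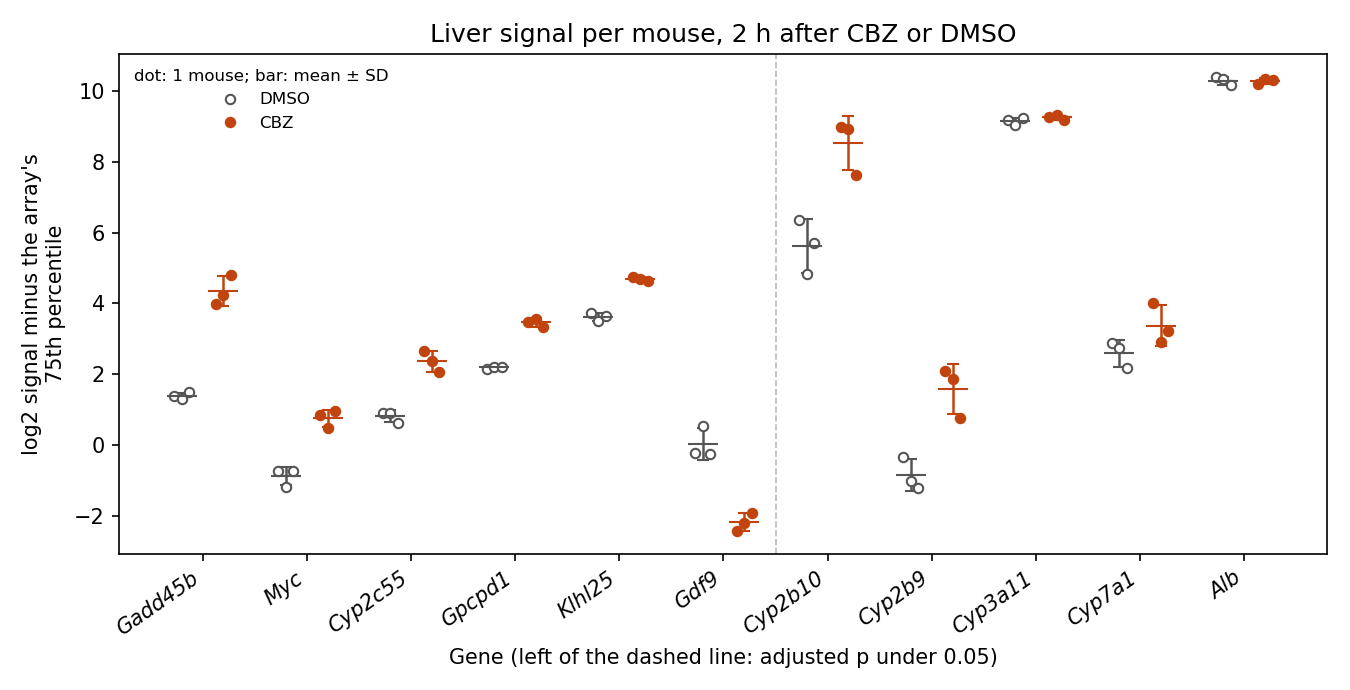
Signal of 11 genes in each liver, as log2 signal minus the array's 75th percentile on the vertical axis, with 1 dot per mouse (open for DMSO, filled for CBZ) and bars for the mean ± SD of 3 mice. The 6 genes left of the dashed line passed an adjusted p of 0.05 and the 5 to its right did not. Gadd45b had a mean of 1.40 ± 0.09 SD in the DMSO mice and 4.35 ± 0.42 SD in the CBZ mice.

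The probes behind these calls lie, on the mouse build mm9 that the array design uses, at chromosome 10, 80394367 to 80394426 for Gadd45b, chromosome 15, 61821417 to 61821476 for Myc, and chromosome 11, 53251307 to 53251366 for Gdf9. Of the other 3 genes that rose, 2 are non-coding transcripts of the array design at 1 locus on chromosome 3. Their brightest probe, at 21973396 to 21973455, rose 2.68-fold (1.42 ± 0.16), and 2810416G20Rik, a clone-named gene that the array probes at the same position, was at 1.47 ± 0.19 (limma's adjusted p = 0.052). The nearest gene there with another kind of name, Tbl1xr1, lay 135122 bp away. The remaining transcript, without a symbol, was probed on chromosome 6 at 141802114 to 141802173, where the nearest named gene was Slco1a4, and rose 2.95-fold (1.56 ± 0.19). These 3 had an adjusted p of 0.030, 0.040 and 0.043 in limma. A dimmer probe passed the threshold while the brightest probe did not for 3 further genes, named after their values were seen. A second probe of Alas1, which encodes the first enzyme of haem synthesis, rose 4.05-fold and its brightest probe was 2.00-fold higher (limma's adjusted p = 0.0082 and 0.17). A dim probe of Chka, the choline kinase gene, was at least 3.03-fold lower and its brightest probe 1.77-fold lower (limma's adjusted p = 0.018 and 0.13). Both probes of DXBay18, a multicopy X-linked gene, were higher, by 6.19-fold and 6.09-fold (limma's adjusted p = 0.041 and 0.056).

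With slide row as a covariate, which leaves CBZ replicate 1 against the 3 DMSO mice, the log2 fold change was 2.60 for Gadd45b, 1.72 for Myc, 1.84 for Cyp2c55, 1.28 for Gpcpd1, 1.12 for Klhl25 and -2.44 for Gdf9, whose value is inexact because it was not well above background in CBZ replicate 1. Limma's adjusted p for that comparison was 0.037 for Gadd45b and over 0.05 for the other 5, and 2 genes rose and 2 fell in all. Row 2 held CBZ arrays only and gives no comparison of its own. For genes and lists alike, the values with this covariate rest on 1 CBZ array, which is assumed to vary like the others, and they cannot separate row from mouse. The counts also depended on single mice: 16 genes rose and 5 fell without CBZ replicate 1, 1 rose and 2 fell without DMSO replicate 2, and 1 rose and 0 fell without DMSO replicate 1 and again without CBZ replicate 3, where 573 and 470 genes were lower at an unadjusted p under 0.05 in limma. Limma called 0 genes in either direction without DMSO replicate 3, where 1067 were higher and 970 lower at an unadjusted p under 0.05, and 0 without CBZ replicate 2, where 858 were higher and 755 lower. By chance 852 of the 17047 genes would pass that unadjusted threshold, in both directions together, and 1528 did with no mouse left out. A split of the arrays into 3 and 3 that mixed the groups gave 3319, so 1528 is no measure of a treatment effect. With the array median in place of the 75th percentile, which is the scaling of the authors' table, 44 genes rose and 45 fell, so that 49.4% of the calls were rises against 88.9% here. That scaling put the median log2 fold change of all probes at -0.11. Its moderated test had 89408 degrees of freedom against 8.62 here, so it used a variance common to all probes. Its p-values therefore do not measure each gene's spread between mice. With quantile normalisation 3 genes rose and 1 fell.

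Because fewer than 5 genes passed in the downward direction, the 8 with the smallest unadjusted p were also read out, and apart from Gdf9 these failed the correction. Ccn1, which encodes a matricellular protein, was 2.15-fold lower (-1.10 ± 0.15). Pdgfrl, a gene related to the receptor of platelet-derived growth factor, was 4.56-fold lower (-2.19 ± 0.32). Siah2, which encodes a ubiquitin ligase, was 1.89-fold lower (-0.92 ± 0.14). Zbtb12, a zinc finger gene, and Etfbkmt, which encodes a methyltransferase acting on an electron transfer flavoprotein, were 1.81-fold and 1.73-fold lower. The other probe of Etfbkmt went the opposite way, by 0.46 ± 0.17. Vpreb1, part of the surrogate light chain of B cell precursors, and Slc27a3, of the fatty acid transport protein family, were not well above background on any CBZ array and were at least 2.18-fold and 1.80-fold lower. With normexp the log2 fold changes were smaller, at -0.58 for Vpreb1, -0.44 for Slc27a3, -0.55 for Ccn1 and -0.43 for Zbtb12. The values for Vpreb1 and Slc27a3 fall short of their bounds, which hold only for the background subtraction used here. Limma's adjusted p with normexp was 0.0025 for Etfbkmt, 0.0035 for Pdgfrl, 0.013 for Siah2, 0.032 for Vpreb1 and 0.033 for Ccn1. It stayed over the threshold for Zbtb12 (0.092) and Slc27a3 (0.12). In the report's fit limma's adjusted p ran from 0.056 for Ccn1 to 0.080 for Slc27a3. In each of these 7 genes all 3 CBZ values lay below all 3 DMSO values, which choosing genes by the smallest p favours.

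Targets of the nuclear receptors CAR and PXR, which switch on drug metabolism in liver, were higher in CBZ than other genes. Of the 31 measured, 22 were higher and 9 lower, with a mean log2 fold change of 0.42 and a median of 0.15. Gadd45b and Cyp2c55 rose when adjusted over all genes, and 5 rose when adjusted over the list alone. The other 3 of these were Cyp2b10, the classical CAR-induced cytochrome P450, at 7.44-fold higher (2.89 ± 0.44), its neighbour Cyp2b9 at 5.39-fold higher (2.43 ± 0.35), and Alas1 at 2.00-fold higher (1.00 ± 0.21). Over all genes limma's adjusted p was 0.066 for Cyp2b10, 0.065 for Cyp2b9 and 0.17 for Alas1, so these 3 missed the threshold there. Cyp3a11, the main PXR-regulated cytochrome P450 of mouse liver, was at 0.10 ± 0.12 (limma's adjusted p = 0.93). Por, which encodes the reductase that supplies these enzymes with electrons and was named after its value was seen, was at -0.02 ± 0.15. The list mean of each of the 3 CBZ mice lay above all 3 DMSO mice. Camera, which compares a list with all other genes, gave this list an adjusted p of 0.00012 over 39 lists at a preset correlation between genes of 0.01. With an estimated correlation the adjusted p = 0.974, a value that the adjustment gave to all 39 lists. For the 9 lists called at the preset, the estimated correlation ran from 0.039 for gluconeogenesis to 0.43 for interferon-stimulated genes. Camera's unadjusted p with it ran from 0.083 for CAR and PXR targets to 0.34 for interferon-stimulated genes. Without the 5 genes that rose over the list, the mean of the other 26 was 0.082. CBZ replicate 1 alone, which is what the slide row covariate leaves, had a list mean of 0.42 and a camera adjusted p of 0.0071, from 1 array. The probes of Cyp2b10 and Cyp2b9 belong to a family of close paralogs whose signals one probe can share.

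Genes of cholesterol and fatty acid synthesis were higher in CBZ as lists, while no member passed the threshold over all genes. In the cholesterol list 22 of 25 genes were higher, with a mean log2 fold change of 0.29. Examples are Hmgcs1, an early enzyme of the pathway, at 0.48 ± 0.18, Pmvk, a mevalonate pathway kinase, at 0.55 ± 0.20, and Hsd17b7, of a late sterol step, at 0.42 ± 0.14. In the fatty acid list 18 of 23 genes were higher, with a mean of 0.33, and 2 rose when adjusted over the list alone. Insig2, whose product retains the SREBP activators in the endoplasmic reticulum, was 2.03-fold higher (1.02 ± 0.19), Pnpla3, a lipid droplet gene, was 3.23-fold higher (1.69 ± 0.40), Fasn, the fatty acid synthase gene, was 2.06-fold higher (1.05 ± 0.31), and Acly, which supplies cytosolic acetyl-CoA, was 1.44-fold higher (0.53 ± 0.16). Camera's adjusted p was 9.8e-06 for cholesterol and 0.00050 for fatty acid synthesis at the preset correlation, and for both lists the adjusted p = 0.974 with an estimated correlation. The slide row covariate gives the values of CBZ replicate 1 alone, with means of 0.52 and 0.31 from 1 array, which had the highest cholesterol mean of all 6. The cholesterol mean was 0.18 without CBZ replicate 1 and 0.19 with median scaling, and the fatty acid list missed the threshold without DMSO replicate 3 (0.27, camera's adjusted p = 0.058). In both lists 1 CBZ mouse lay within the range of the DMSO mice.

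**Figure D2:**
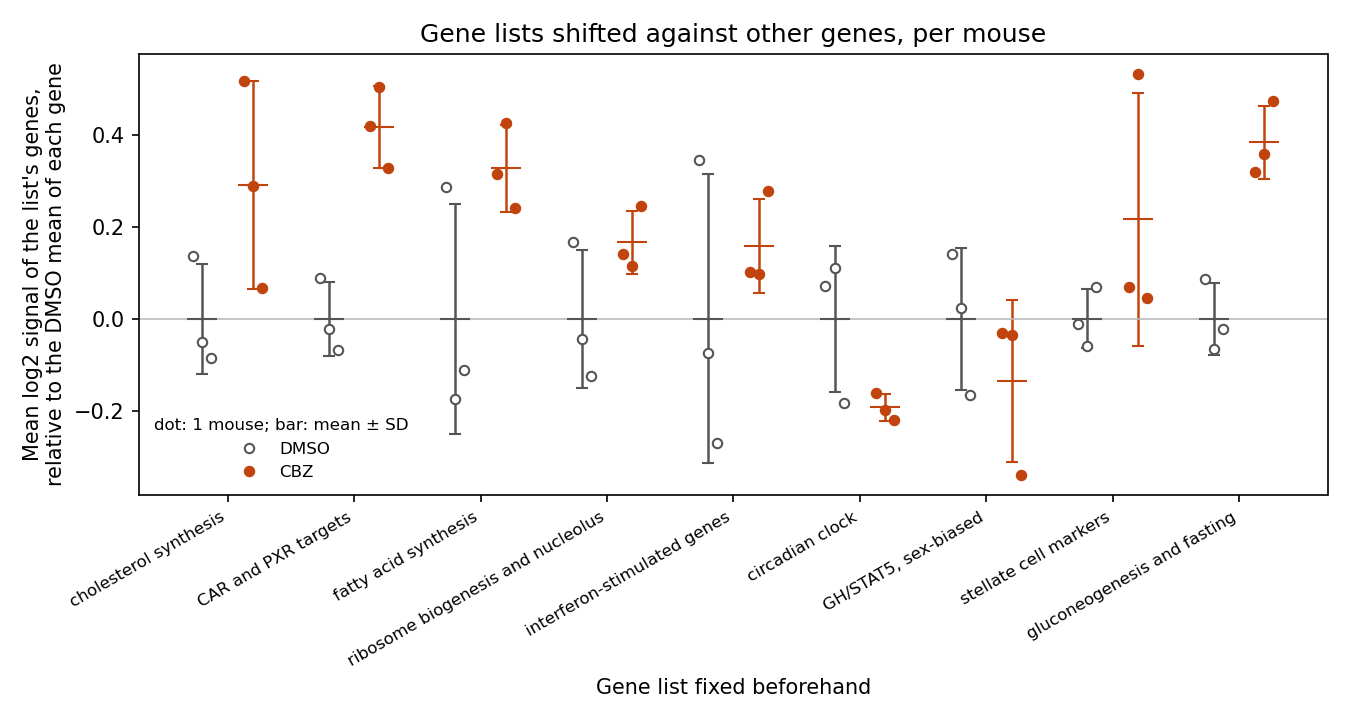
Mean log2 signal of each list's genes per liver, relative to each gene's mean in the DMSO mice, for the 9 lists that passed camera at the preset correlation, with 1 dot per mouse and bars for the mean ± SD of 3 mice. The CBZ mice lay above all DMSO mice for CAR and PXR targets, from 0.33 to 0.51, and for gluconeogenesis and fasting, from 0.32 to 0.47, and overlapped them in the other 7 lists.

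Genes of gluconeogenesis and fasting and of ribosome biogenesis were also higher in CBZ as lists. In the gluconeogenesis and fasting list 11 of 17 genes were higher, none passed over all genes, and 3 rose when adjusted over the list alone. These were Ppp1r3g, which encodes a subunit that targets a phosphatase to glycogen, at 4.05 ± 0.75, G6pc, which encodes the enzyme that releases glucose, at 0.77 ± 0.15, and Igfbp1, a secreted binding protein of insulin-like growth factors, at 0.77 ± 0.16. Irs2, an insulin receptor substrate, was at 0.65 ± 0.27. The list's mean was 0.38 and its median 0.08, and the mean was 0.16 over the genes well above background on all 6 arrays, where camera's adjusted p was 0.094. That filter leaves out Ppp1r3g, which was well above background on 2 of 3 DMSO arrays. Its CBZ values had an SD of 1.70, and normexp lowered its log2 fold change to 2.77. In ribosome biogenesis 24 of 26 genes were higher, with a mean of 0.17 over all 26, and none passed alone. The list mean of DMSO replicate 1, at 0.17, lay above CBZ replicates 1 and 2, at 0.14 and 0.12. It lay below CBZ replicate 3, at 0.25. The nucleolar genes Pes1, Rrp1b, Mybbp1a and Gar1 were at 0.85 ± 0.22, 0.60 ± 0.18, 0.36 ± 0.15 and 0.34 ± 0.14. A dimmer probe of Pes1 was at 0.10 ± 0.19. Median scaling lowered the ribosome biogenesis mean to 0.068. Camera's adjusted p was 0.040 for gluconeogenesis and 0.0062 for ribosome biogenesis at the preset correlation, and for both lists the adjusted p = 0.974 with an estimated correlation. With slide row as a covariate neither passed, at means of 0.32 and 0.14 and camera's adjusted p of 0.14 and 0.12. Gluconeogenesis missed the threshold without DMSO replicate 3 (camera's adjusted p = 0.20) and without CBZ replicate 2 (0.18), and ribosome biogenesis without DMSO replicate 3 (mean 0.11, camera's adjusted p = 0.18) and without CBZ replicate 3 (0.060).

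Interferon-stimulated genes and markers of hepatic stellate cells and fibroblasts were higher as well, again with no member past the threshold alone. Among interferon-stimulated genes 16 of 22 were higher, with a mean of 0.16 over all 22. Ifi44 was at 0.61 ± 0.21, the nucleic acid sensor Zbp1 at 0.48 ± 0.17, the GTPase gene Gbp3 at 0.40 ± 0.12 and the RNA sensor Oas1a at 0.37 ± 0.14. Gbp3 and Oas1a belong to families of close paralogs. Of the 14 stellate cell and fibroblast markers 12 were higher, with a mean of 0.22 over all 14. Hepatocyte growth factor, Hgf, was at 0.56 ± 0.21, the collagen gene Col3a1 at 0.37 ± 0.22, Pdgfrb at 0.33 ± 0.22 and the matrix gene Ecm1 at 0.22 ± 0.17. The interferon mean was highest in DMSO replicate 1, at 0.35, against -0.075 and -0.27 in the other DMSO mice and 0.10, 0.097 and 0.28 in the CBZ mice. Markers of Kupffer cells and macrophages had the same order in the DMSO mice, at 0.64, -0.22 and -0.43. The mean of the stellate markers was 0.53 in CBZ replicate 2 and 0.07 and 0.05 in the other CBZ mice. Camera's adjusted p was 0.012 for interferon-stimulated genes and 0.029 for stellate markers at the preset correlation, and for both lists the adjusted p = 0.974 with an estimated correlation. With slide row as a covariate neither passed, at means of 0.10 and 0.070 and camera's adjusted p of 0.20 and 0.89, and Ecm1 was at -0.078. The interferon list missed the threshold without DMSO replicate 3 (mean 0.024, camera's adjusted p = 0.41), without CBZ replicate 3 (0.10, 0.075) and with median scaling (0.060, 0.052), and its mean was 0.33 without DMSO replicate 1. The stellate list missed it without CBZ replicate 2 (0.058, 0.67), without DMSO replicate 1 (0.21, 0.060) and without DMSO replicate 2 (0.19, 0.055), and its mean was 0.12 with median scaling.

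Circadian clock genes and growth hormone targets were lower in CBZ as lists. Of 17 clock genes 14 were lower, with a mean log2 fold change of -0.19. The activator Clock was at -0.45 ± 0.15, the deubiquitinase gene Usp2 at -0.54 ± 0.22 and the repressor Nr1d1 at -0.50 ± 0.22, while the repressor Bhlhe40 was at 0.38 ± 0.15. Per1, a core repressor of the clock, was at -0.22 ± 0.15. In limma no clock gene passed over all genes or when adjusted over the list alone. In the list of growth hormone and STAT5 targets with sex-biased liver expression 16 of 20 genes were lower, with a mean of -0.14. Only CBZ replicate 3, at -0.34, had a list mean below the lowest DMSO mouse, at -0.17. The cytochrome P450 genes Cyp4a12a and Cyp4a12b, which are higher in male liver, were at -0.73 ± 0.20 and -0.67 ± 0.19. These paralogs and Cyp7b1, an oxysterol hydroxylase at -1.08 ± 0.33 named after its value was seen, were the 3 genes that fell when adjusted over the list alone. In the opposite direction, Cyp2b9 at 2.43 ± 0.35 and Igfbp3, a carrier of insulin-like growth factors, at 0.84 ± 0.18 rose when adjusted over the list alone. No growth hormone target passed over all genes. Camera's adjusted p was 0.012 for the clock and 0.026 for growth hormone targets at the preset correlation, and for both lists the adjusted p = 0.974 with an estimated correlation. With slide row as a covariate neither passed, at means of -0.16 and -0.031 and a camera adjusted p of 0.14 for both. The clock missed the threshold without DMSO replicate 1 (mean -0.16, camera's adjusted p = 0.056) and had a mean of -0.29 with median scaling. Growth hormone targets missed it without DMSO replicate 1 (-0.065, 0.16), without CBZ replicate 3 (-0.033, 0.10) and with median scaling (-0.23, 0.059), while their mean was -0.22 without DMSO replicate 3 and -0.056 without a filter.

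Fry, which tests a list by itself, called none of the lists in 1 direction, with a lowest adjusted p of 0.45 for CAR and PXR targets and for gluconeogenesis. Fry's test for change in either direction gave an adjusted p of 0.00024 for CAR and PXR targets, 0.029 for growth hormone targets and 0.033 for gluconeogenesis. The other lists that camera called missed it, from 0.15 to 0.77. Some lists that camera did not call passed it, such as p53 targets (0.029) and glycolysis and hypoxia (0.033). The other genes read out in any case showed no call. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.78 ± 0.29 (limma's adjusted p = 0.44). Nqo1, an oxidative stress gene, was at -0.23 ± 0.20, Hmox1, which encodes the haem-degrading oxygenase, at 0.07 ± 0.28, and Alb, the albumin gene, at -0.01 ± 0.13, with limma's adjusted p from 0.87 to 0.99. Hmox1 was at -0.03 with median scaling, and Alb at 0.01 when scaled over detected spots. Cyp1a1, the classical target of the aryl hydrocarbon receptor, and Fos, an immediate early gene, had no probe well above background on all arrays of a group. Camera did not call the other 30 lists. Among these were aryl hydrocarbon receptor targets, at an adjusted p of 0.84, the oxidative stress targets of NRF2 and the unfolded protein response, both at 0.74, the acute phase response, at 0.51, and secreted hepatocyte proteins, at 0.87. Markers of other liver cells did not pass either, at 0.26 for Kupffer cells and macrophages, 0.97 for neutrophils, 0.18 for lymphocytes, 0.89 for endothelium, 0.18 for cholangiocytes and 0.87 for blood. In CBZ replicate 1 alone, as left by the slide row covariate, camera's adjusted p was 0.016 for cholangiocyte markers, at a mean of 0.41, and 0.037 for lymphocyte markers, at 0.26. In the other CBZ mice these means were 0.0038 and 0.12 for cholangiocytes and 0.12 and 0.018 for lymphocytes.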

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

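The scaling over detected spots and the array's median intensity as a covariate were chosen only after the data were seen. Among the named genes and the lists no called result changed sign under any alternative run, while the uncalled Alb, Hmox1 and Ecm1 did under some. Over 18 alternative fits Gadd45b kept its direction in all and passed an adjusted p of 0.05 in limma in 15, with log2 fold changes from 2.60 to 3.13. Gpcpd1 passed in 10, Myc and Cyp2c55 in 8 and Klhl25 in 4 of 18, and Gdf9 in 7 of 17. Median scaling and the authors' table are the same scaling but count as 2 of these fits. All of these genes except Klhl25 passed in both. Over the named genes and alternatives, 825 values stayed on their side of the threshold, 55 lost it and 48 gained it. Normexp gave 59 genes higher and 44 lower, quantile normalisation 3 higher, median scaling and the authors' table each 44 higher and 45 lower, the filter on all 6 arrays 23 higher and 7 lower, the intensity trend with robust eBayes 63 higher and 71 lower, slide row as a covariate 2 higher and 2 lower, an adjusted p under 0.10 28 higher and 14 lower, and scaling over detected spots and the median intensity as a covariate each 3 higher and 0 lower, with 645 and 908 genes lower at an unadjusted p under 0.05. Chance gives 852 of the 17047 genes kept an unadjusted p under 0.05, in both directions together. Without a filter limma called 0 genes higher and 0 lower among 55658 probes, with 1058 higher and 542 lower at an unadjusted p under 0.05. Under median scaling the moderated test had 89408 degrees of freedom against 8.62 in the report's fit, and it also moved the median log2 fold change of all probes to -0.11. Which of these shifted the counts was not tested, nor were the causes of the other shifts. Leaving out 1 mouse gave 0 to 16 genes higher and 0 to 5 lower. It also moved some uncalled genes by over 1.5 times. Without DMSO replicate 2 Irs2 was at 0.38, Fasn at 0.66, Pdgfrb at 0.12 and Per1 at -0.12, and without DMSO replicate 3 Hgf was at 0.35 and Zbp1 at 0.32. Without CBZ replicate 1 Cyp7a1 was at 0.46, Hmgcs1 at 0.32 and Pmvk at 0.36, without CBZ replicate 2 Col3a1 was at 0.12, and without CBZ replicate 3 Usp2 was at -0.30 and Col3a1 at 0.60. Nqo1 was at -0.011 without DMSO replicate 1 and -0.40 without DMSO replicate 2. Normexp lowered Pnpla3 to 0.78, Rrp1b to 0.35, Igfbp3 to 0.34, Ifi44 to 0.25, Hgf to 0.25 and Pdgfrb to 0.17, and gave -0.30 for Clock, -0.25 for Nr1d1 and -0.15 for Nqo1.

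The number of lists called was 9, where 1528 single genes had an unadjusted p under 0.05 in limma against 852 expected by chance. Splits of the 6 arrays that mixed the groups reached 3319 such genes and 17 lists, so neither count sets treatment apart. The number of lists ran from 7 to 12 with 1 mouse left out. With an estimated correlation 0 lists were called, at a camera adjusted p of 0.974 for all 39. With fry's test for change in 1 direction 0 were called (lowest adjusted p 0.447). In those tests the list means stay as reported, at 0.29 for cholesterol synthesis, 0.42 for CAR and PXR targets, 0.33 for fatty acid synthesis, 0.17 for ribosome biogenesis, 0.16 for interferon-stimulated genes, -0.19 for the clock, -0.14 for growth hormone targets, 0.22 for stellate markers and 0.38 for gluconeogenesis. With slide row as a covariate 6 of these lists missed the threshold, at 0.14 for ribosome biogenesis, 0.10 for interferon-stimulated genes, -0.16 for the clock, -0.031 for growth hormone targets, 0.070 for stellate markers and 0.32 for gluconeogenesis. The same fit, in which CBZ replicate 1 is the only CBZ array compared, called 8 lists. Of these 5 were not called in the report, namely markers of cholangiocytes (0.41, camera's adjusted p = 0.016) and of lymphocytes (0.26, 0.037), phase II enzymes (-0.20, 0.013), the heat shock response (-0.22, 0.016) and autophagy (-0.12, 0.049). Other lists gained a call under other scalings: immediate early genes with normexp (0.17, 0.019) and median scaling (0.12, 0.0022), ATF4 and CHOP targets (0.20, 0.00019) and PPARa targets (0.086, 0.011) with median scaling, cytosolic ribosomal proteins with quantile normalisation (0.075, 0.022), oxidative phosphorylation with normexp (-0.089, 0.018) and over detected spots (-0.047, 0.037), and autophagy with normexp (-0.080, 0.047). Under median scaling each list mean less the median of all genes stayed at its main value, such as 0.30 for ATF4 and CHOP targets. Median scaling and the authors' table ended the calls of interferon-stimulated genes at 0.060 and growth hormone targets at -0.23. No filter ended those of interferon-stimulated genes at 0.13 and gluconeogenesis at 0.38, and the filter on all 6 arrays those of stellate markers at 0.19 and gluconeogenesis at 0.16. Scaling over detected spots ended that of gluconeogenesis at 0.41, and the median intensity as a covariate that of growth hormone targets at -0.095. The cause was not tested. With 1 mouse left out the means ran from 0.18 to 0.40 for cholesterol synthesis, 0.37 to 0.46 for CAR and PXR targets, 0.24 to 0.47 for fatty acid synthesis, 0.11 to 0.25 for ribosome biogenesis, 0.024 to 0.33 for interferon-stimulated genes, -0.28 to -0.14 for the clock, -0.22 to -0.033 for growth hormone targets, 0.058 to 0.30 for stellate markers and 0.34 to 0.43 for gluconeogenesis.

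Nothing in the labels says that the replicate numbers pair the mice, and so few mice cannot decide it. The deviations of same-numbered mice from their group means correlated at -0.24, 0.02 and 0.18, and 2 of 6 arrays correlated best with their own number. With the replicate number as a block 6 genes were higher and 1 lower, 3 of the 9 genes called without it were among them, and 9 lists were called. Signal over background limits the dim genes: the 75th percentile of an array was 9.89 to 12.3 times its median local background.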

Other observations

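The tests of slide row and of shared signal for Gadd45b, Cyp2b10, Cyp2b9, Cyp2c55 and Alas1 were chosen only after the result was seen. Apart from Myc, Ccn1, Gadd45b, Cyp2b10, Cyp2b9 and Cyp2c55, the genes of the next paragraphs were also picked after their values were seen.

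Immediate early genes, which respond to stimuli without new protein synthesis, went both ways. Of the 24 measured 16 were higher and 8 lower, Myc rose over all genes, and 5 rose and 5 fell when adjusted over the list alone. With Myc, the transcription factor genes Klf2 at 1.08 ± 0.30, Klf4 at 1.04 ± 0.23 and Fosl2 at 0.80 ± 0.17 and the antiproliferative gene Btg2 at 0.69 ± 0.24 rose over the list. Egr1 at -1.55 ± 0.28, Ccn1 at -1.10 ± 0.15, Junb at -0.62 ± 0.20, Ier2 at -0.58 ± 0.14 and Socs3 at -0.51 ± 0.18 fell over it. For the list camera gave an adjusted p of 0.095, and adjusted p = 0.974 with an estimated correlation, while fry's test for change in either direction gave an adjusted p of 0.00052. Camera's adjusted p was 0.019 with normexp and 0.0022 with median scaling, and in CBZ replicate 1, the CBZ array in row 1, the list mean was -0.015.

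In the list of ATF4 and CHOP targets, genes of the integrated stress response, 8 of 17 were higher and 9 lower, and 5 rose and 1 fell when adjusted over the list alone. Gdf15, a stress-induced cytokine, was 6.09-fold higher (2.61 ± 0.38), Trib3, a pseudokinase gene, 2.42-fold higher (1.28 ± 0.19) and Ddit4, an inhibitor of mTOR signalling, 2.99-fold higher (1.58 ± 0.45), while Atf4 itself was at -0.46 ± 0.14 and Ddit3, which encodes CHOP, at -0.53 ± 0.20. Over all genes limma's adjusted p was 0.065 for Gdf15, 0.066 for Trib3 and 0.30 for Ddit4. For this list camera gave an adjusted p of 0.24, and adjusted p = 0.974 with an estimated correlation, but 0.00019 with median scaling. The list's mean less the median of all genes was 0.30 under either scaling. Fry's test for change in either direction gave it an adjusted p of 0.026. Gadd45a, a relative of Gadd45b, was not well above background in any DMSO mouse and was at least 2.77-fold higher in CBZ, with an adjusted p of 0.21 in limma. Dnajb1, a heat shock gene, was 2.00-fold lower and Ahr, the aryl hydrocarbon receptor gene, at 0.73 ± 0.15, and both missed the threshold, with limma's adjusted p at 0.13 and 0.16.

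That Gadd45b, Cyp2b10, Cyp2b9, Cyp2c55 and Alas1 were higher through CAR was not tested on held-out genes. Of the other 26 members of the list 17 were higher and 9 lower, with a mean over all 26 of 0.082 and an SE of 0.034. For Cyp2b9 beside Cyp2b10 shared signal cannot be told apart from a rise of both genes. Their log2 fold changes differed by 0.47 with an SE of 0.32, which either would allow. Slide row cannot be told apart from treatment with 1 CBZ array in row 1. In that array the genes lay a median of 2.43 above the highest DMSO mouse, where the largest DMSO SD was 0.76.

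The cholesterol and fatty acid synthesis lists may be higher because single mice differ rather than through CBZ. The lowest CBZ mouse lay below the highest DMSO mouse in both lists, by a difference of -0.070 for cholesterol and -0.046 for fatty acid synthesis, and the group means lay 1.61 and 1.73 pooled SDs apart. As a reason for the lists lying above other genes the scaling is argued against, since under quantile normalisation the list mean less the median of all genes was at least 1.05 times its value, though median scaling lowered the means themselves to 0.19 and 0.23. Slide row stays open, since the CBZ array in row 1 lay 0.38 above the highest DMSO mouse for cholesterol and 0.028 for fatty acid synthesis, and it is 1 array. An effect of CBZ also stays open.

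Sp5, Tbx3 and Rnf43, targets of Wnt signalling, were at -0.98 ± 0.18, -0.78 ± 0.13 and -0.80 ± 0.14, with limma's adjusted p from 0.099 to 0.14, which raised the hypothesis that Wnt targets fell. Held-out Wnt targets argued against a fall of the class, with a mean of -0.037 and an SE of 0.12, but only 5 of 14 were measured. Myc and Ccnd1 (0.94 ± 0.35), also Wnt targets, were higher. Of the pericentral hepatocyte markers, a list seen earlier that holds Tbx3 and depends in part on Wnt, 10 of 12 were lower, with a mean of -0.12 over all 12. The adjusted p was 0.18 in camera, 0.86 in fry's test for change in 1 direction and 0.033 in fry's test for change in either direction. In the CBZ array of row 1 the 3 genes lay a median of 0.67 below the lowest DMSO mouse, against a largest DMSO SD of 0.22. That met the bound set beforehand against slide row, but the bound was too weak, as the row holds 1 CBZ array, so slide row may still account for part of the difference.

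Rarb, a retinoic acid receptor gene, and Cyp26a1, which clears retinoic acid, were at 1.10 ± 0.14 and 1.05 ± 0.20 (limma's adjusted p = 0.052 and 0.15). The hypothesis that retinoic acid targets rose was argued against by held-out targets, with a mean of 0.081 and an SE of 0.080 over the 8 of 13 measured, of which 4 were higher and 4 lower.

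The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 9 genes and the highest other split 0, so that 1 of 10 splits gave as many. For lists the real split called 9 and the highest other split 17, and 5 of 10 splits gave as many. At an unadjusted p under 0.05 in limma the real split had 1528 genes. The split of DMSO replicate 1 with CBZ replicates 2 and 3 from the other arrays had 1413, and the splits not named here had 277 to 917. The split of DMSO replicates 1 and 2 with CBZ replicate 2 from the other arrays had 3319 and called 0, which points to a structure of the arrays apart from treatment. The first principal component, with 33.5% of the variance, put those 3 arrays at -30.0, -22.2 and -7.66 and the other 3 between 13.1 and 25.4. Those 3 arrays also had the lowest median intensities, with 27.5 as the lowest, against 40.3, 45.5 and 44.2 in the other 3.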
